A study of Mus musculus with 12 samples.

How the data were processed

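Whole brains of mouse embryos at embryonic day 14.5 were profiled by sequencing of polyadenylated RNA, with 12 libraries from 12 embryos, per the labels. The embryos belong to 2 experiments, named LC1 and RKI in the sample titles, with 3 wild-type and 3 mutant embryos in each. The 4 groups are LC1 wild type (embryos 6, 26 and 73), LC1 knockout (7, 22 and 71), RKI wild type (A2, A9 and A16) and RKI homozygous (A1, A10 and A18). The LC1 embryos are all female, and each RKI group holds 1 female and 2 males, per the labels. The labels' protocol states that mutant and wild-type embryos were matched by sex and litter, and that libraries were made with an oligo-dT kit. No label names the litters. Tail tissue was kept for genotyping, per the labels' protocol, and gene counts do not read the deletion or the knock-in, so the genotypes were not checked here.

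The authors deposited a table of counts per gene, a table of RPKM per gene, a table of estimated counts per transcript and tables of their own comparisons. The submitters' processing notes name STAR 2.0.4b, Subread, featureCounts 1.4.5, edgeR and limma without their roles. The genome build, the annotation release, the strand setting of the counting and the tool behind the transcript estimates are not given in the sources used here. The deposited gene counts are whole numbers, and the table lists 41264 rows for 40690 gene identifiers. The 574 repeated rows carry the same counts as the row they repeat, and 1 row per identifier was kept. The deposited RPKM values follow the counts divided by the library total to within 0.013% over 12441 genes, which was checked on the tables. The deposited estimated counts per transcript are not whole numbers and were rounded before testing. The deposited percent GC content of each gene is an annotation and was not used. The authors' deposited tables of comparisons hold a log2 fold change and p-values in the layout of limma, and their model is not given in the sources used here. The authors' RKI tables give wild type minus homozygous, which was checked on the values, and the sign was turned here so that a positive value is higher in the mutant.

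Gene counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the low-count filter filterByExpr by group, robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. All 12 libraries entered 1 fit with 4 group means and a term for sex, which left 7 residual degrees of freedom. The filter kept 16002 genes, and the common biological coefficient of variation was 6.94%. The comparisons were LC1 knockout against wild type, RKI homozygous against wild type, the difference between these effects, male against female within the RKI libraries, and RKI wild type against LC1 wild type. Standard errors were taken from the log2 fold change and its F statistic, and intervals are at 95%. The rounded transcript estimates of 47772 transcripts were tested in the same way, without a model of the uncertainty of the estimates. Levels are given as CPM, the count scaled by the TMM-adjusted library total, as mean ± SD. P-values of the gene and transcript tests rest on the spread between embryos within groups, pooled over the 4 groups of 3 embryos. Those of camera, described next, compare the members of a list with the other genes. With the preset correlation camera takes genes as nearly independent, so its p-values do not measure the spread between embryos alone.

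Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and beside it with camera using a correlation estimated from the data and with fry. Of 28 lists, 27 had at least 5 measured members and were tested, with adjustment over the lists of a comparison. They cover the genes around Pou3f2 on chromosome 4, a POU and PAX6 network, radial glia, intermediate progenitors, pallial neurons, subpallial and GABAergic neurons, amygdala and hypothalamus regions, midbrain and hindbrain regions, oligodendrocyte precursors, proliferation, synapse and excitability, and genes at bipolar disorder loci. Others hold markers of erythroid blood, endothelium and pericytes, microglia and macrophages, meninges and mesenchyme, choroid plexus, skin, cartilage and muscle, and eye. The remaining lists are immediate early and stress genes, hypoxia and glycolysis, mitochondrially encoded genes, replication-dependent histones, ribosomal proteins, cholesterol synthesis and interferon response. A list of pituitary and olfactory epithelium genes had too few measured members. The groups, comparisons, tests, lists, the rule for named genes and all alternatives not said to be added later were fixed before the data were examined.

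The genes named for a comparison are Pou3f2 and the list around it as a summary, up to 10 genes higher and 10 lower past the threshold, or else the genes with the smallest p until 10 are named. For each list that passed, the 3 members with the smallest p are named, and at most 2 for other lists. For sex, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the 3 autosomal genes with the smallest p are named. Some results that this rule names are not reported. Gene positions are from GENCODE M21 on GRCm38, matched by gene identifier for 40254 genes. The authors' build is not known to be the same, so positions describe that annotation only.

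Total counts per library ran from 18192984 to 25632111 in LC1 and from 20247871 to 26566769 in RKI. TMM factors lay between 0.985 and 1.01. Pairs of libraries within a group differed by more than counting noise, with chi-square values of 3.05 to 20.3 per degree of freedom, so no library was counted as a repeat of another. The edgeR tests, and camera for LC1, RKI and sex, were run on simulated counts. These were drawn with the real means, library sizes and fitted spread. Fry and the alternatives below were not run on them. Of 67, 67 and 66 simulated genes changed 1.25, 1.5 and 2-fold, the test called 22.4%, 70.1% and 84.8% for LC1, and 43.3%, 73.1% and 89.4% for RKI. For the difference between the effects it called 7.46%, 47.8% and 83.3%, and for sex 14.9%, 65.7% and 80.3%. For RKI wild type against LC1 wild type it called 19.4%, 53% and 81.8% of 67, 66 and 66 genes. Of simulated transcripts changed 2-fold, it called 3.08% of 65 for LC1 and 7.81% of 64 for RKI. Of all calls in the simulated genes, 14 of 132 for LC1, 12 of 149 for RKI, 7 of 99 for the difference, 11 of 118 for sex and 8 of 110 for the wild types were of unchanged genes. These shares of 7.07% to 10.6%, from 1 draw for each comparison, are above the nominal 5%. For transcripts 1 of 3 calls was false for LC1 and 0 of 5 for RKI. The simulation draws genes independently of each other, which real genes are not. It also gives each gene the same mean in all 12 libraries apart from the added changes. Of simulated unchanged genes, 4.93% for LC1 and 4.92% for RKI had an unadjusted p under 0.05 by edgeR. In the real comparisons 2.09% and 1.92% of genes had, so the shares recovered may be overstated. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no filter on low counts, a filter of CPM 1 in 3 libraries, no robust estimation, no sex term, the libraries of 1 experiment alone, a threshold of 0.1, limma on log2 RPKM with pseudocounts of 0.1 and 1 for Pou3f2, a block over embryos with neighbouring numbers, and leaving out each library in turn. The pairs for the block come from the embryo numbers in the titles. Deviations from the group means correlated at 0.142, 0.182 and 0.119 within the RKI pairs and at 0.112, 0.098 and 0.195 within the LC1 pairs. Each RKI pair was thus above 0.1 and 1 LC1 pair was not. Embryos of other numbers correlated at -0.11 to 0.001 in RKI and -0.14 to 0.034 in LC1. Sex was not removed from these deviations, and both embryos of each RKI pair are of the same sex. Giving the blocked count beside the RKI genes was decided after its calls were seen. The deposited RPKM values per transcript were not used here.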

Results

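Polyadenylated RNA was sequenced from whole brains of 12 mouse embryos at embryonic day 14.5, with 3 embryos in each of 4 groups. LC1 is a conserved non-coding element between genes, upstream of Pou3f2, which encodes a neuronal transcription factor of the POU family. In the LC1 experiment 3 embryos with the element deleted were compared with 3 wild types. In the RKI experiment 3 embryos homozygous for a knock-in of a human sequence variant in this element were compared with 3 wild types. The title of the series links the variant to cognitive performance and bipolar disorder. Total counts per library ran from 18192984 to 26566769. Counts of Xist, which is expressed from the inactive X chromosome, lay at 26806 or more in each of the 8 libraries of female embryos and at 225 or less in each of the 4 libraries of males, so all 12 libraries matched the sex in their labels.

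Pou3f2, the gene next to the element, was at nearly the same level in all groups. Pou3f2 (ENSMUSG00000095139) lies on chromosome 4 at 22482780 to 22488366, minus strand, in GENCODE M21 on GRCm38. Its level was 93.4 ± 5.94 CPM in LC1 wild types and 100 ± 6.71 CPM in LC1 knockouts (SD, n = 3 each). It was 95.3 ± 3.79 CPM in RKI wild types and 94.8 ± 3.01 CPM in RKI homozygotes (SD, n = 3 each). The log2 fold change was 0.10 with SE 0.065 and a 95% interval of -0.04 to 0.24 for LC1, or a fold of 1.07 with an interval of 0.975 to 1.18. For RKI it was -0.01 with SE 0.064 and an interval of -0.14 to 0.13, or a fold of 0.995 with an interval of 0.906 to 1.09. Adjusted p by edgeR's quasi-likelihood test over all genes was 1 in both comparisons, and adjusted over the list alone it was 0.864 for LC1 and 0.909 for RKI. An exact two-sided permutation test of log2 CPM gave p = 0.3 for LC1 and p = 0.8 for RKI, where 3 embryos against 3 allow no p under 0.1. The permutation test used neither sex nor litter, and the edgeR fit used sex but not litter, which no label names. The LC1 value was 0.05 without wild type 6, 0.06 without knockout 71 and 0.15 without knockout 22, where the unadjusted p was 0.0433 and the adjusted p 0.999. The RKI value changed sign, to between 0.00 and 0.02, when A2, A9, A10 or A18 was left out. The authors' deposited table gives 0.10 for LC1 with an unadjusted p of 0.121 and -0.01 for RKI with an unadjusted p of 0.88.

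**Figure D1:**
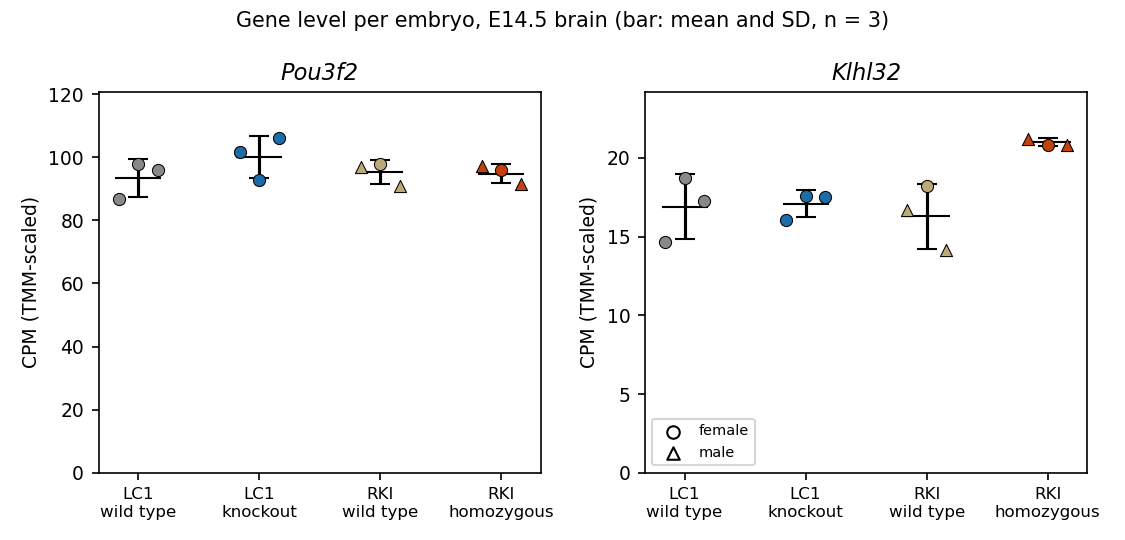
CPM of Pou3f2 and Klhl32 (vertical axes) in each embryo of the 4 groups (horizontal axis), with circles for females, triangles for males, a long bar for the mean and whiskers for the SD over 3 embryos. Pou3f2 means lie between 93.4 and 100 CPM, and Klhl32 is at 21 CPM in RKI homozygotes and at 16.3 CPM in RKI wild types.

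Of the 17 genes fixed as the list around Pou3f2, 16 were measured. In LC1 knockouts 12 were higher and 4 lower, with log2 fold changes of -0.08 to 0.18, and 0 passed the threshold adjusted over the list alone or over all genes. In RKI homozygotes 9 were higher and 7 lower, with values of -0.23 to 0.36, and 1 passed adjusted over the list alone, while 0 passed over all genes. That gene was Klhl32, which encodes a protein of the kelch-like family and lies at 24612554 to 24851124 on chromosome 4. Klhl32 was at 16.3 ± 2.06 CPM in RKI wild types and 21 ± 0.238 CPM in RKI homozygotes (SD, n = 3 each), a log2 fold change of 0.36 with SE 0.099. Its adjusted p by edgeR was 0.0308 over the list alone, 0.0423 over the 22 genes measured within 3 Mb of Pou3f2 and 1 over all genes. The call over the list alone was lost with only the 6 RKI libraries and without A1, A16 or A18. In LC1 the Klhl32 value was 0.02, and the difference between the effects, 0.34 with SE 0.143, had an adjusted p of 0.437 over the list alone. The list as a whole passed in neither comparison, with camera adjusted p of 0.134 for LC1 and 0.395 for RKI, but it passed for LC1 without knockout 7 or wild type 26 and for RKI without A18. With an estimated correlation its adjusted p was 0.833 and 0.903 with all libraries, and 0.534, 0.636 and 0.937 in these 3 settings.

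**Figure D2:**
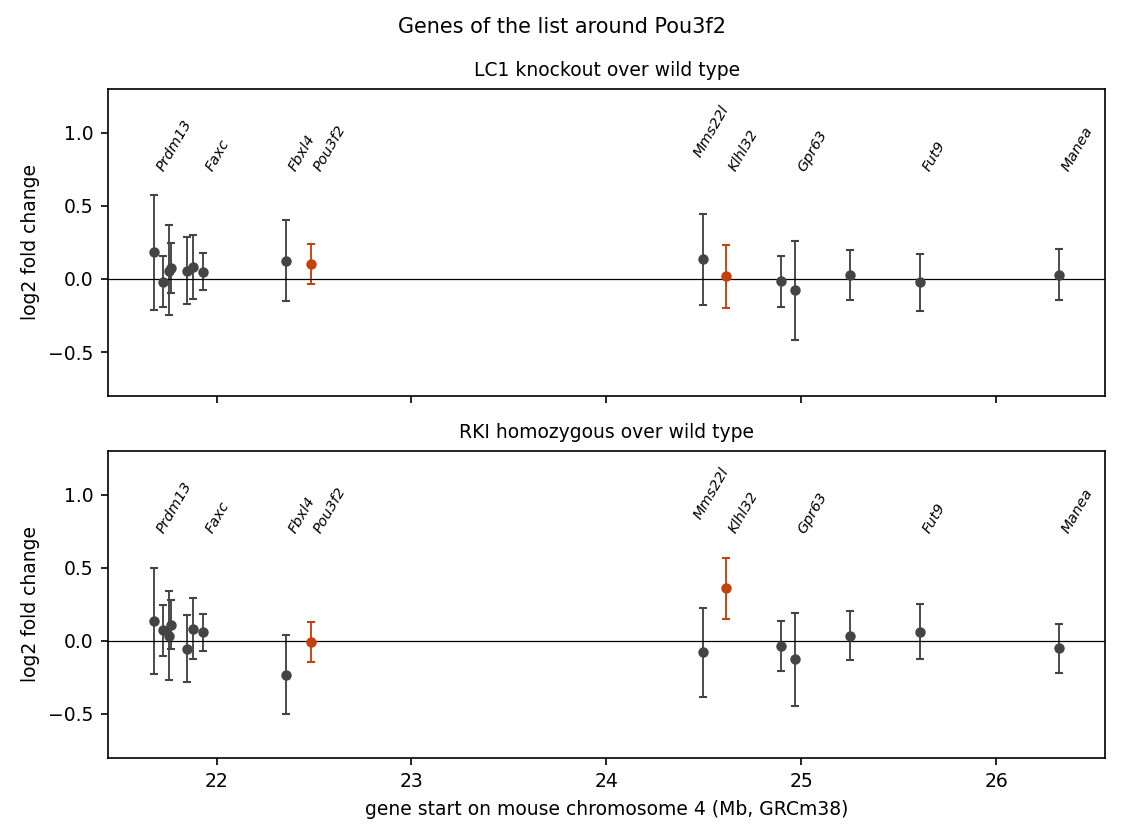
Log2 fold change (vertical axes) of the 16 measured genes of the list around Pou3f2 by the start of the gene on mouse chromosome 4 in Mb (horizontal axis), with 95% intervals as bars, for LC1 above and RKI below; Pou3f2 and Klhl32 are in orange and names are given for some genes. The interval of Pou3f2 includes 0 in both comparisons, and Klhl32 has a value of 0.36 in RKI.

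Deletion of LC1 was next compared over all genes, to ask which transcripts differ in the embryonic brain without the element. None of the 16002 genes passed the threshold by edgeR, and DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05, edgeR listed 334 genes, DESeq2 183 and limma-voom 330, where 800 are expected by chance for independent genes. By edgeR there were 719 without wild type 73 and 217 without wild type 6. The smallest adjusted p was 1 by edgeR. The 10 genes with the smallest p, none past the threshold, included 2 of the microglia and macrophage list. These were C1qa of the complement system at -0.51 (SE 0.148) and the mannose receptor Mrc1 at -0.33 (SE 0.095), which had -0.18 without wild type 6. Also among the 10 were Ncf4, a subunit of the phagocyte oxidase, at -1.44, and Oscar, a receptor of osteoclasts, at 1.71, both under 1 CPM in each LC1 group. Tekt1, a protein of ciliary microtubules, had -0.57, at 7.53 ± 0.53 CPM in wild types and 5.09 ± 0.748 CPM in knockouts (SD, n = 3 each). Insm1 and Rcor2, which act in neuronal differentiation as a transcription factor and a corepressor, had 0.28 (SE 0.084) and 0.21 (SE 0.063). The others were Nexn at -0.84, Zfp951 at -0.63 and Gm16054 at -0.75. The authors' deposited table for LC1 has 0 genes past an adjusted p of 0.05 and 1117 at an unadjusted p under 0.05, with a smallest adjusted p of 0.137.

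As groups, microglia and macrophage genes fell in LC1 knockouts: all 15 measured members were lower, with a mean log2 fold change of -0.23 (camera adjusted p = 3.49e-06; adjusted p = 0.615 with an estimated correlation). C1qa and Mrc1 passed adjusted over the list alone, each at 0.0232, and P2ry12 had -0.29. Intermediate progenitor genes rose, 10 of 10 with a mean of 0.14 (adjusted p = 0.00105; 0.615 as adjusted p with an estimated correlation), led by Insm1, which passed adjusted over the list alone at 0.0454, then Dll3 at 0.25 and Btg2 at 0.14. Pallial neuron genes rose, 14 of 16 with a mean of 0.08 (adjusted p = 0.00105; adjusted p = 0.615 with an estimated correlation), with Tbr1 at 0.15, Neurod2 at 0.13 and Fezf1 at 0.22. Meninges and mesenchyme genes fell, 18 of 20 with a mean of -0.13 (adjusted p = 0.00105; adjusted p = 0.833 with an estimated correlation), with Col1a2 at -0.21, Aldh1a2 at -0.23 and Ogn at -0.26. Choroid plexus genes fell, 11 of 14 with a mean of -0.12 (adjusted p = 0.0203; adjusted p = 0.833 with an estimated correlation), with Kcne2 at -0.24, Calml4 at -0.43 and Folr1 at -0.20. Mitochondrially encoded genes fell, 13 of 17 with a mean of -0.12 (adjusted p = 0.00565; adjusted p = 0.833 with an estimated correlation), with mt-Nd6 at -0.15, mt-Tm at -0.62 and mt-Nd4 at -0.17. Ribosomal protein genes fell, 67 of 80 with a mean of -0.09 (adjusted p = 0.000668; adjusted p = 0.833 with an estimated correlation), with Rpl31 at -0.34, Rps7 at -0.23 and, against the direction, Rpl28 at 0.21. No list passed with an estimated correlation or by fry.

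The LC1 list results depended on the wild-type embryo 6, whose library had the highest score of the 6 LC1 libraries for the microglia, meninges, choroid plexus, mitochondrial and ribosomal lists, at 0.286, 0.208, 0.205, 0.148 and 0.212 in log2 units, and the lowest for intermediate progenitors, at -0.208. Without this library 2 of the 7 lists passed; the microglia list had -0.12 with an adjusted p of 0.00908, and the means of the intermediate progenitor, meninges, choroid plexus, mitochondrial and ribosomal lists were 0.08, -0.05, -0.04, -0.02 and -0.01 with calls lost. Without knockout 71 the meninges, choroid plexus and mitochondrial calls were lost at -0.06, -0.07 and -0.08, without knockout 22 the ribosomal call at -0.07, and without wild type 73 the pallial call at 0.06, whereas without knockout 7 there were 11 lists that passed. Lists newly past the threshold were the list around Pou3f2, erythroid blood, endothelium and skin without knockout 7, the list around Pou3f2 without wild type 26, proliferation without knockout 22 or wild type 73, and subpallial neurons without knockout 71. With only the 6 LC1 libraries proliferation also passed. The meninges mean was -0.23 without knockout 7, the mitochondrial mean -0.22 without knockout 22, and the intermediate progenitor and ribosomal means 0.22 and -0.13 without wild type 73. With all 12 libraries none of the other lists passed, with adjusted p of 0.134 to 0.836. Members higher in the knockout were 15 of 21 for the POU and PAX6 network, 11 of 17 for radial glia, 15 of 21 for subpallial and GABAergic neurons, 13 of 21 for amygdala and hypothalamus regions, 5 of 14 for midbrain and hindbrain regions, 4 of 8 for oligodendrocyte precursors and 18 of 26 for proliferation. They were 13 of 26 for synapse and excitability, 9 of 14 for bipolar disorder loci, 6 of 16 for erythroid blood, 3 of 18 for endothelium and pericytes, 2 of 7 for skin, 5 of 14 for cartilage and muscle and 5 of 9 for eye. They were 11 of 23 for immediate early and stress genes, 12 of 24 for hypoxia and glycolysis, 6 of 18 for histones, 12 of 22 for cholesterol synthesis and 9 of 14 for interferon response. The test's direction was opposite to the mean for the synapse and eye lists, and opposite to the mean and the median for the hypoxia list.

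**Figure D3:**
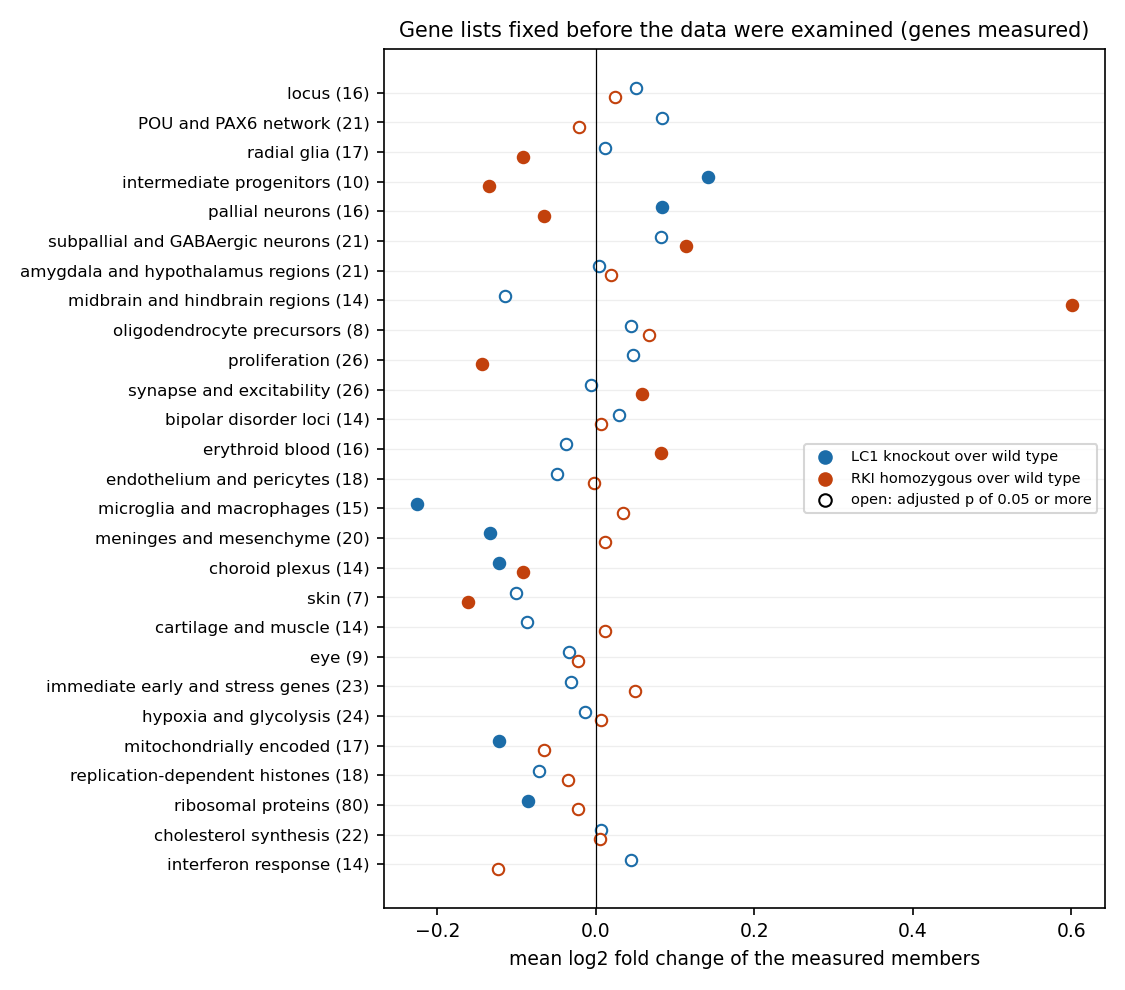
Mean log2 fold change of the measured members (horizontal axis) for the 27 lists (vertical axis, number measured in brackets), with LC1 in blue and RKI in orange; filled circles have a camera adjusted p under 0.05 with the preset correlation and open circles do not. The midbrain and hindbrain list has a mean of 0.60 in RKI and the microglia list a mean of -0.23 in LC1, and no list passed with an estimated correlation.

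The RKI knock-in was compared in the same way, to ask which transcripts differ in embryos that carry the variant on both alleles. None of the 16002 genes passed by edgeR, and DESeq2 and limma-voom also called 0. With a block over embryos with neighbouring numbers, which no label ties to litters, 3 genes passed, Crb1 at an adjusted p of 0.0289, Esrrb and Ubxn2b, the last 2 named after their values were seen. At an unadjusted p under 0.05, edgeR listed 307 genes, DESeq2 177 and limma-voom 311. By edgeR there were 501 without A2, 187 without A1, and 1323 and 1342 without A9 and A10, the last 2 above the 800 expected by chance. The 10 genes with the smallest p, none past the threshold in the 12-library fit without the block, were led by Shox2, a homeobox factor, at 0.53 (SE 0.117) and at 0.35 without A16, with 13.3 ± 3.3 CPM in wild types and 19.2 ± 0.992 CPM in homozygotes (SD, n = 3 each). Crb1, a protein of cell polarity, had -1.04 (SE 0.212), with 18.8 ± 3.76 and 9.21 ± 4.14 CPM (SD, n = 3 each). In log2 CPM Crb1 lay at 4.45, 3.87 and 4.32 in wild types A2, A9 and A16. It lay at 3.81, 2.9 and 2.68 in homozygotes A1, A10 and A18, and at 4.44 to 4.77 in the LC1 libraries. Levels thus differed within each RKI genotype, with A9 and A1 close together, and the cause was not tested. Lhx1, a LIM-homeobox factor, had 0.29, the fatty acid binding protein gene Fabp3 0.52, Klhl32 0.36, the RNA-binding protein gene Rbm47 -0.65 and the signalling factor gene Wnt3a -0.71. Gm20667 had -0.73, and Cd300c2 and Tmem30b, both under 1 CPM, had -1.39 and -1.61. With no filter on low counts, Crb1, Shox2 and Rbm47 passed. Without A1, Crb1 passed at an adjusted p of 0.00221, and without A9 or A10, 2 other genes passed, Mir99ahg and Wdfy1, named after their values were seen. A9 and A10 are the only RKI females, so with the sex term both of these settings compare the 4 males. The authors' deposited table for RKI has 0 genes past an adjusted p of 0.05 and 722 at an unadjusted p under 0.05, with a smallest adjusted p of 0.138.

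Midbrain and hindbrain regional genes were higher in RKI homozygotes than in RKI wild types: 12 of 14 measured members were higher with a mean of 0.60 (camera adjusted p = 2.38e-08, or 0.759 with an estimated correlation). The RKI wild types A2, A9 and A16 had low scores for this list, at -0.345, -0.239 and -1.393. Homozygotes A1, A10 and A18 lay at 0.121, 0.174 and -0.293, none above the LC1 libraries, at 0.055 to 0.667. The list was fixed with 32 members, so the result stands for the 14 measured ones alone. Gata3 at 1.25, Gata2 at 0.45 and Tal1 at 0.68, transcription factors of GABAergic midbrain neurons and also of blood, passed adjusted over the list alone, each at 0.0338. Proliferation genes fell, 26 of 26 with a mean of -0.14 (adjusted p = 9.81e-06; adjusted p = 0.903 with an estimated correlation), with Aurkb at -0.26, Cdc20 at -0.19 and Birc5 at -0.24. Radial glia genes fell, 15 of 17 with a mean of -0.09 (adjusted p = 0.00389; adjusted p = 0.759 with an estimated correlation), with Emx2 at -0.19, Lhx2 at -0.19 and Hes1 at -0.30. Pallial neuron genes fell, 13 of 16 with a mean of -0.07 (adjusted p = 0.00389; adjusted p = 0.759 with an estimated correlation), with Fezf2 at -0.16, Neurod2 at -0.14 and Nfix at -0.18. Intermediate progenitor genes fell, 9 of 10 with a mean of -0.14 (adjusted p = 0.0399; adjusted p = 0.828 with an estimated correlation), with Neurog1 at -0.47, Mfap4 at -0.17 and Gadd45g at -0.22. Subpallial and GABAergic genes rose, 19 of 21 with a mean of 0.11 (adjusted p = 0.00565; adjusted p = 0.903 with an estimated correlation), with Gad2 at 0.17, Slc32a1 at 0.23 and Maf at 0.09. Synapse and excitability genes rose, 23 of 26 with a mean of 0.06 (adjusted p = 0.00565; adjusted p = 0.903 with an estimated correlation), with Scn2a at 0.12 and Nefl at 0.11. Markers of other tissue moved too: erythroid blood genes rose, 12 of 16 with a mean of 0.08 (adjusted p = 0.0406; adjusted p = 0.903 with an estimated correlation), with Bpgm at 0.12, Klf1 at 0.46 and Hbb-bs at 0.17. Choroid plexus genes fell, 9 of 14 with a mean of -0.09 (adjusted p = 0.0406; adjusted p = 0.903 with an estimated correlation), with Slc4a5 at -0.43, Clic6 at -0.29 and Aqp1 at -0.18. Skin genes fell, 6 of 7 with a mean of -0.16 (adjusted p = 0.00349; adjusted p = 0.759 with an estimated correlation), with Epcam at -0.43, Perp at -0.36 and Krt18 at -0.27. No list passed with an estimated correlation or by fry.

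The wild-type embryo A16 stood apart from the other libraries, at 26.1 on principal component 1. This component also parted the sexes. The other males A1, A2 and A18 lay at 10.76, 13.36 and 12.85, and the females at -11.97 to -2.57. A16 had a midbrain and hindbrain score of -1.393 and a proliferation score of 0.397, the lowest and highest of the 12 libraries. Without A16, 6 lists passed, among them the bipolar disorder loci and ribosomal proteins, which had not passed with all 12 libraries; the midbrain and hindbrain list kept its call at 0.36 with an adjusted p of 0.0269, the proliferation and synapse lists turned to 0.04 and -0.03, and the radial glia, intermediate progenitor, subpallial and choroid plexus calls were lost at -0.05, -0.09, 0.06 and -0.02. Other libraries mattered as well: the pallial call was lost without A2, A9 or A10, the skin call without A9 or A10, the radial glia and synapse calls without A18 and the synapse call without A1. The subpallial call was lost without A2 and turned to -0.02 without A18, and the erythroid call was lost without A2 or A18 and turned to -0.13 and -0.12 without A9 and A10. The intermediate progenitor call was lost without A1, A2 or A18 and with only the 6 RKI libraries (adjusted p = 0.0691), and the choroid plexus call without A1, A9, A10 or A18. Without A2 the means of the midbrain, proliferation and synapse lists were 0.91, -0.23 and 0.10, and without A1 those of the proliferation and erythroid lists were -0.09 and 0.20. In the comparison of the 4 males that leaving out A9 or A10 makes, the proliferation, radial glia, intermediate progenitor, subpallial and synapse means were -0.29, -0.16, -0.26, 0.24 and 0.15. Without A16 the pallial and erythroid means were -0.11 and 0.29. The ribosomal list also passed without A2, and the list around Pou3f2 and the mitochondrial list without A18. With all 12 libraries none of the other lists passed, with adjusted p of 0.0992 to 0.931. Members higher in homozygotes were 12 of 21 for the POU and PAX6 network, 12 of 21 for amygdala and hypothalamus regions, 4 of 8 for oligodendrocyte precursors, 9 of 14 for bipolar disorder loci, 7 of 18 for endothelium and pericytes, 11 of 15 for microglia and 11 of 20 for meninges. They were 7 of 14 for cartilage and muscle, 4 of 9 for eye, 14 of 23 for immediate early genes, 12 of 24 for hypoxia and glycolysis and 3 of 17 for mitochondrially encoded genes. They were 10 of 18 for histones, 27 of 80 for ribosomal proteins, 13 of 22 for cholesterol synthesis and 3 of 14 for interferon response. The test's direction was opposite to the median for the POU and PAX6 and histone lists, to the mean for the cartilage list and to both for the hypoxia list.

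The effects of the deletion and of the knock-in were compared directly. None of the 16002 genes differed between them past the threshold by edgeR, DESeq2 or limma-voom, with 388, 238 and 387 genes at an unadjusted p under 0.05. By edgeR there were 658 of these without wild type 73, and 959 and 958 without A9 and A10. Without A1, 1 gene passed, Crb1, and without A9 or A10, which leaves the 4 RKI males to compare, 1 gene passed, Wdfy1, both named after their values were seen. Several lists differed, with adjusted p from 2.15e-05 for pallial neurons and for midbrain and hindbrain regions to 0.0421 for radial glia. Proliferation, microglia, intermediate progenitors and meninges lay between these, and none of the 7 passed with an estimated correlation, where adjusted p ran from 0.479 to 0.908. Leaving out each library in turn, added after the data were seen, the proliferation mean went from -0.19 to -0.01 without A16 with its call lost. The meninges mean went from 0.15 to 0.05 without wild type 6 and its call was lost, as also without knockout 71, A2 or A18. The radial glia call was lost without wild type 6 or 26, knockout 71, A1, A2, A16 or A18. The other 4 lists kept their calls in all 12 settings, though the midbrain mean went from 0.72 to 0.47 without A16, and without wild type 6 the microglia mean went from 0.26 to 0.15 and the intermediate progenitor mean from -0.28 to -0.22. Newly past the threshold in at least 1 setting were erythroid blood, ribosomal proteins, synapse, subpallial neurons, endothelium, skin, interferon response, the POU and PAX6 network and bipolar disorder loci. The test's direction was opposite to the mean and the median for the amygdala, oligodendrocyte, eye and histone lists, to the mean for the hypoxia list and to the median for the cholesterol list. Across 16002 genes the log2 fold changes of the comparisons had a Pearson r of -0.0392 and a Spearman rho of -0.048, a description across genes, which are not independent replicates.

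Among transcripts, 0 of 47772 passed for LC1 and 0 for RKI by edgeR, with 1418 and 1172 at an unadjusted p under 0.05 and smallest adjusted p of 0.158 and 0.0588. Without knockout 22, 1 transcript of Rnf157, named after its value was seen, passed for LC1, and for RKI 3, 3 and 7 passed without A1, A9 and A10. Chosen after the values were seen, 4 of the 5 RKI transcripts with the smallest p belonged to predicted genes of chromosome 4, Gm10600 at -2.71 (SE 0.249), Gm5859 at -4.29 (SE 0.41), Gm13301 at -6.75 (SE 0.879) and Gm2163 at -1.29 (SE 0.179). Gm10600, Gm5859 and Gm13301, with Gm17081 beside them, summed to 3.33 ± 0.37 CPM in RKI homozygotes and 36.7 ± 3.51 CPM in RKI wild types (SD, n = 3 each). The sum ran from 26.7 to 48.9 CPM over the 9 libraries of the other groups. These genes share stretches of sequence with other transcripts, so the assignment of reads among them is uncertain.

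**Figure D4:**
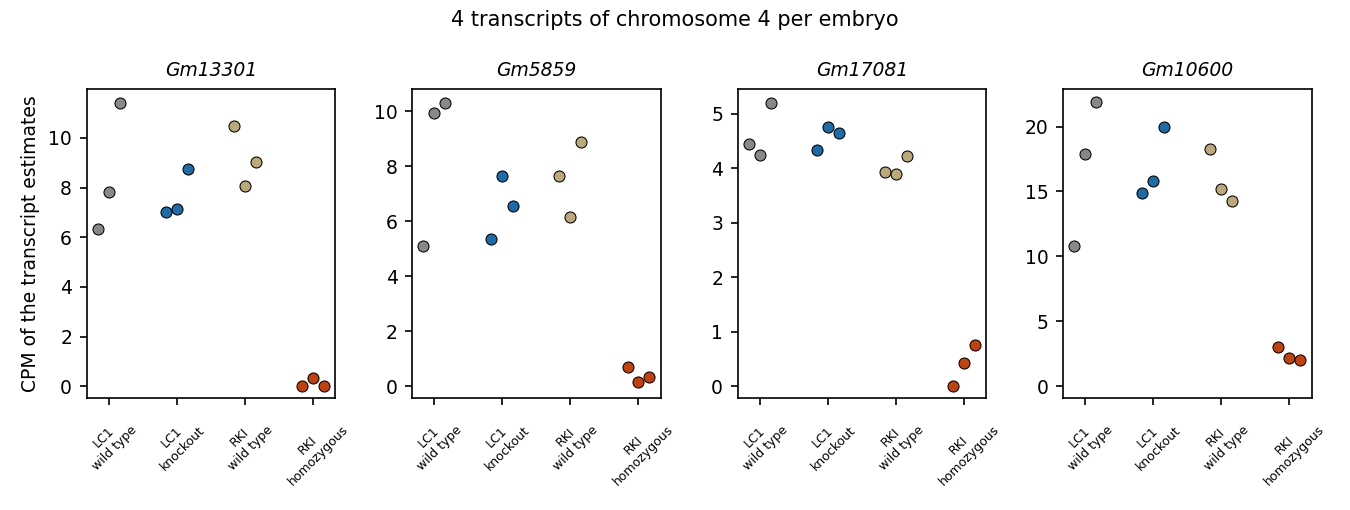
CPM of the estimated counts (vertical axes) of 4 transcripts of chromosome 4 in each embryo of the 4 groups (horizontal axis), each point an embryo. The sum of the 4 is 3.11 to 3.76 CPM in the RKI homozygotes and 26.7 to 48.9 CPM in the other 9 libraries.

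Male and female embryos, both present only in the RKI groups, served to show what the fit can call. Of 16002 genes, 8 passed by edgeR, 6 higher in males and 2 lower, while DESeq2 called 12 and limma-voom 8. Xist had a log2 fold change of -7.72 (SE 0.116), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 8.27, 7.74, 8.43 and 8.53. Gm29650, read in males alone, and Kdm6a, which escapes X inactivation, at -0.45 (adjusted p = 0.00429), also passed and are named after their values were seen. Hmgb1, a chromatin protein, had 0.41 (adjusted p = 0.184) and Rspo3, an activator of Wnt signalling, had 0.40 (adjusted p = 0.589), neither past the threshold by edgeR, while DESeq2 called Hmgb1 and edgeR with no filter on low counts called both. Hmgb1 has many processed pseudogenes, so its count is uncertain. Of the lists, proliferation was higher in males with 26 of 26 members (adjusted p = 0.00021), pallial neurons with 14 of 16 (0.0248) and mitochondrially encoded genes with 12 of 17 (0.0458), and midbrain and hindbrain was lower with 10 of 14 (0.0136) and synapse with 23 of 26 (0.00879). With an estimated correlation the adjusted p was 0.778 for each of these 5. The test's direction was opposite to the median for the cartilage list. Without A16, a male, 2 lists passed, pallial neurons and erythroid blood, an alternative added after the data were seen, and with an estimated correlation the adjusted p was 0.994 for both.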

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

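The tests on gene lists with other size factors, the locus counts under other settings, the effect correlation under other settings, the sex lists without A16, the lists of the difference between the effects under other settings, the estimated correlation and fry with a library left out and the block for named genes were added after the data were seen. Under the alternatives run, the named LC1 genes kept their side of the threshold in 149 of 149 values and the named RKI genes in 142 of 147, with 5 newly past it, for Crb1 (3 settings), Shox2 and Rbm47. The lists that passed kept their call in 53 of 63 values for LC1, with 10 lost, and in 62 of 90 for RKI, with 23 lost and 5 of opposite sign. For the difference between the effects they kept it in 72 of 84, with 12 lost.

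With no filter on low counts, 4 genes passed for LC1 (Capn11, Gm21887, Hist1h2af and Ide), 26 for RKI, 17 for the difference between the effects, 45 for sex and 28 for RKI wild type against LC1 wild type, and the effect correlation was 0.012. This setting tested 27458 genes and the prior degrees of freedom became infinite, and the cause of the added calls was not tested. With no filter, and with a filter of CPM 1 in 3 libraries, 2 RKI transcripts passed, of Gm10600 and Gm5859. With only the 6 RKI libraries 0 locus genes passed. With an estimated correlation, and by fry, 0 lists passed for LC1, 0 for RKI, 0 for sex and 0 for the difference between the effects, and with each library left out in turn 0 passed for LC1, RKI and the difference. With only the 6 wild types, AC149090.1 and Wdfy1 passed for RKI wild type against LC1 wild type, 2 genes of which 0 were shared with the 12-library fit.

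With a block over embryos with neighbouring numbers 3 RKI genes passed (Crb1, Esrrb and Ubxn2b) and 0 LC1 genes, and the counts of lists stayed at 7 and 10. Among embryos of the other genotype each correlated best with its neighbour. Sex was left in these deviations, and A9 and A10 are the only RKI females. For that pair sex and a shared litter cannot be told apart. Among the RKI males, neighbours correlated at 0.142 and 0.119 and the other pairs at -0.021 and 0.001. For these males and the LC1 embryos, all female, this is a hint of shared litters from the data and not from the labels.

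Leaving out 1 library at a time, the calls were 0 to 2 genes for RKI (2 without A9 or A10), 0 to 1 for the difference between the effects, 1 to 2 for RKI wild type against LC1 wild type (1 without 6, 26, 73 or A9), 0 to 1 locus genes for RKI, 2 to 11 lists for LC1, 6 to 7 lists for RKI, 5 to 9 lists for the difference between the effects, 2 lists for sex without A16, 0 to 1 transcripts for LC1 and 0 to 7 for RKI. The Pou3f2 value ran from -0.042 to 0.017 for RKI and from 0.047 to 0.152 for LC1. In RKI, the list means ran from -0.015 to 0.241 for subpallial neurons, -0.291 to 0.037 for proliferation, -0.029 to 0.151 for synapse and -0.125 to 0.292 for erythroid blood. Leaving out A9 or A10 leaves 1 female in RKI, which the sex term takes up, so both are nearly the same comparison of 4 males. The cause of the other changes was not tested. Simulated 1.25-fold changes were mostly missed at this depth and n, so small effects on single genes stay open. Larger simulated changes were missed in part, and the real tests gave fewer small p-values than the simulation. Larger effects on single genes thus stay open too.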

Other observations

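Tests of other splits of the libraries were planned with their bounds and the sorting of RKI splits by sex and by pair written after the counts were seen, and the tests of the chromosome 4 transcripts, Gabra2, Wdfy1 and A16 were chosen after the results were seen.

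Wild types of the 2 experiments differed in Gabra2, a subunit of the GABA-A receptor, at 21.1 ± 1.63 CPM in LC1 and 38.8 ± 3.03 CPM in RKI (SD, n = 3 each), a log2 fold change of 0.88 with an adjusted p of 0.000594. Of 16002 genes, 2 passed by edgeR, the other being the predicted gene Gm28438 of chromosome 1, with 623 at an unadjusted p under 0.05 (1186 without A16), while DESeq2 and limma-voom also called 2. With only the 6 wild types neither passed, while AC149090.1 and Wdfy1 did. Gm28438 lost its call without embryo 6, 26 or 73, and without A9 neither gene passed and Mir99ahg did. Neighbours of Gabra2 on chromosome 5 had log2 values of 0.10 for Gabrg1, -0.12 for Gabra4 and 0.36 for Gabrb1, of which none passed. These genes were chosen after their values were seen.

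Gabra2 lay at 4.21 to 4.52 log2 CPM in the 6 LC1 libraries and at 5.17 to 5.39 in the 6 RKI libraries. Wdfy1, a gene of chromosome 1 chosen after its values were seen, lay at 6.04 in A1, 6.02 in A9, 5.94 in A10, 6.01 in A18, 4.46 in A2 and 4.27 in A16, and at 4.41 to 4.65 in the LC1 libraries. Sex is argued against for Wdfy1, since RKI males differed by 1.776 in log2, and more GABAergic tissue is argued against for Gabra2, since that list had a median of 0.049 with 14 of 21 other members higher. Still open for Wdfy1 are the knock-in genotype, since the overlap of 0.083 between the groups rests on A9 alone, and a change across its neighbourhood, where the verdict turns on a floor: the highest SD among genes within 1 Mb was 0.185 with a floor of 2 in mean log2 CPM and 0.469 without it, against a bound of 0.425 that was also set after the values were seen, so nothing is excluded. Inherited variants that differ between the embryos may underlie both, a hypothesis that the Gabra2 gap of 0.649 between the experiments leaves open, as C57BL/6J is known to carry a variant that lowers Gabra2, but no sequence was read here.

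The 4 chromosome 4 transcripts that were low in RKI homozygotes lie at 42216908 to 42242685, 19.7 Mb from Pou3f2, and Gm13301 had 2 reads over 12 libraries in the gene table while the others had 0. The test of a difference in depth or scaling could not decide. It gave a median of 0.018 over 70 genes within 2 Mb, from scaled gene counts whose median over all genes was 0.0012. Scaling holds such a median near 0, and the transcript estimates were scaled apart from the gene counts. Estimated counts before scaling argue against depth or scaling for 3 of the transcripts. Homozygotes had 51 to 81 for Gm10600, 4 to 19 for Gm5859 and 0 to 8 for Gm13301. Wild types had 366 to 535, 171 to 227 and 224 to 307. Transcript totals overlapped, at 23443489 to 30658434 in homozygotes and 25590714 to 29312666 in wild types. Reads moving between transcripts with shared sequence stay open. Counting the 4 themselves, 23 transcripts share 31-mers with them, and 16 of these have estimates. Those beside the 4 share from 3.8% (Fam205a4) to 92.6% (Gm3893) of their 31-mers, so not all are close copies. The sum over the 16 was also lower in homozygotes (log2 ratio -1.483, 28.6 ± 1.83 against 79.9 ± 9.97 CPM, SD, n = 3 each). The 7 without estimates share 8.2% to 86.7% of their 31-mers. A stretch of chromosome 4 inherited with the knock-in may account for the transcripts and stays open: 2.74% of 219 genes within 25 Mb of Pou3f2 had an unadjusted p under 0.05 against 1.91% of the other genes (two-sided Fisher's exact test, p = 0.319). The knock-in itself was not told apart from such a stretch.

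The RKI lists may rest on the wild-type embryo A16. For midbrain and hindbrain genes this stays open: the mean was 0.60 with A16 and 0.358 without it, and the call was kept with the preset correlation. With an estimated correlation the adjusted p was 0.759 with all libraries and 0.694 without A16. The scores of the other libraries overlap, at -0.345 and -0.239 in wild types A2 and A9 and at 0.121, 0.174 and -0.293 in homozygotes A1, A10 and A18. For proliferation genes the mean without A16 was 0.037, of opposite sign with the call lost, which is in line with that library as the source; whether it differs by dissection, stage or biology was not tested.

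With 3 against 3 libraries there are 10 splits, so no share under 0.05 can be had. For lists, 5 of 10 LC1 splits gave at least the real 7, with 11 as the highest other, and 2 of 10 RKI splits gave the real 10, with 10 as the highest other. For RKI wild type against LC1 wild type, 1 of 10 gave the real 2 genes, with 1 as the highest other. Where the real count is 0 every split gives at least as many, so the counts say nothing about chance: 10 of 10 for LC1 genes, RKI genes, LC1 transcripts and RKI transcripts, with 0, 540, 2 and 44 as the highest others, and 100 of 100 drawn splits for the difference between the effects, with 1187 as the highest other, from a draw with the same RKI split as the 540. In 4 of the 10 RKI splits both females fall on 1 side, and with the sex term these compare 1 male with the other 3. The split with 540 genes is of this kind, with A16 as the lone male, which points to A16 standing apart and not to a split comparable with the real one. In the 6 splits with 1 female on each side, and in the 4 that part all 3 pairs of neighbouring numbers, 0 genes and 0 transcripts passed. Of 100 drawn splits 64 gave an effect correlation at least as far from 0 as the real 0.0392 in size, with 0.215 as the highest other, so chance is not excluded for the correlation.

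In the gene table, mt-Co2, mt-Atp8, mt-Co3 and mt-Nd4l had 0 counts over 12 libraries, mt-Atp6 had 1 and mt-Nd3 had 8, while mt-Co1 had 1409679. Ide, chosen after its values were seen, was at 6.78 log2 CPM in LC1 wild type 6, 6.81 in LC1 wild type 26 and 7.04 in A16, and at 6.10 to 6.33 in the other 9 libraries.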
